A study of Drosophila melanogaster with 10 samples.

How the data were processed

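RNA was measured by RNA-seq in whole male larvae of Drosophila melanogaster of the third instar, raised at 25 °C. The 10 libraries were grouped from their labels into 5 genotypes of 2 libraries each: the control stock y w, the mutant y w, atf3[76], and that mutant with 1 copy of dfoxo[25J13], of rel[E20] or of atf3[A]. The labels name these alleles and give no molecular lesion, and they do not say what atf3[A] is. They call the 2 libraries of a genotype biological replicates without saying that they came from separate cultures, so p-values measure only the spread between these samples.

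Per the submitters' processing notes, TopHat 1.3.2 and Cufflinks 1.1.0 were named and the genome build was BDGP R5 (dm3); annotation, strandedness and filters are not given in the sources used here. The authors deposited 4 tables of 14148 records, each with FPKM values (fragments scaled to transcript length and to the number of mapped fragments) for 1 mutant genotype and for y w. The y w columns were identical in the 4 tables. The lowest deposited FPKM value was 1 in every library, so a value of 1 is a floor, and what the authors placed there is not stated. The deposited tables also give a score named fold change and a call of regulation for each record. The authors' fold change matched the ratio of the group means within 2% for between 99.4% and 99.7% of the records, and the lowest fold change of a call was 1.5. The rule behind those calls is not given in the sources used here, and they were used only as the authors' counts. Coordinates are those of the deposited tables. The reference genome at hand is of another build and was not used for coordinates.

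Records that shared a symbol were collapsed to 1 gene, which concerned 94 symbols and left 13995 genes with 13873 gene identifiers. Of these, 2437 were listed at 1 in all 10 libraries, and 5191 overlapped another gene in position. Because strand is not stated, reads of overlapping genes cannot be told apart, and the values of such genes are uncertain. Of the genes named below, Rel, LysD, LysE, mge, Lcp65Ab1, Oscp, Hrb98DE, IM10, LysC, LysP, CG5506, CG6686, CG14610 and CG42306 overlap another gene. So do y, Lmpt, CG9084, CG32549, CG15012, Hexo1, CG9509, CG9512, Fst, CG4783 and the small nucleolar RNAs named below. All columns of sample values were used.

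Read depth is not given. A short gene takes values that are whole multiples of what 1 fragment is worth, so relative depth was read from the steps of small nucleolar RNA values at 9 gene lengths between 130 and 160 bp, with a tolerance of 0.03 and between 24 and 47 values per library. No library repeated another: across all pairs, at most 1 gene above the floor had an identical value in both.

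The plan fixed before the data were examined allowed for tables of the authors' own comparisons or for values per sample. The files held FPKM per sample, so the planned test for that unit was used. Each mutant genotype was compared with y w in a fit of those 2 groups alone, with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), over genes above 1 in at least 1 library of the fit. P-values were adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Genotypes with a second allele or element were compared with atf3[76] by a direct contrast in one limma model of all 5 groups. Many genes listed at 1 in both libraries of a group are given with each library's value. A log2 difference printed for such a gene measures no fold.

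A total of 35 gene lists were fixed before the data were examined, covering immune, metabolic, digestive, cuticle, detoxification, stress, hormone and tissue-marker genes. Of the 18 female-specific genes listed, 4 were tested against y w, and 3 in the genotype with atf3[A]. Each list's median log2 fold change was given a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, adjusted over all 140 tests. Calls within a list were compared with other tested genes by Fisher's exact test, two-sided, and were also counted with p-values adjusted over the list alone. The random-list test treats genes as independent. As an alternative chosen after seeing the data, camera from limma was run with a preset correlation of 0.01 and with an estimated correlation between genes. Calls were also compared between the 6 chromosome arms and within 1 Mb of Atf3, foxo and Rel, by Fisher's exact test in 36 tests. The same y w libraries enter all comparisons, so overlaps and correlations between comparisons are given beside the mean over 50 simulations of unchanged groups against shared controls.

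The named genes were set by a rule fixed before the data were examined. Atf3, foxo, Rel, y and w are named always. Among called genes with an FPKM of at least 5 in the higher group and 0.5 in the lower, the 10 with the largest change in each direction are named. From each list with at least 2 calls, up to 4 called members with the highest FPKM are named. For the contrasts with atf3[76], the 10 largest differences past the threshold with an FPKM of at least 5 in either genotype are named. Members of a list that passed only when adjusted over the list alone, and genes given only with all 5 groups in one model, were chosen after their values were seen. So were TotC, TotA, Dpt, Mtk and AttA.

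The limma steps were tested on simulated data in which 100 genes each were changed 4-fold or 16-fold. Changed genes had a mean FPKM of at least 5. The noise was normal, with no step that lists abundant genes at the floor of 1. Against y w, calls recovered 47% of 16-fold genes for atf3[76], 56% with dfoxo[25J13], 58% with rel[E20] and 51% with atf3[A], over 11542 to 11549 genes. For 4-fold genes the shares were 5%, 15%, 8% and 1%. Unchanged genes made up 1 of 53, 9 of 80, 1 of 67 and 2 of 54 calls in the same order. These shares do not carry over to genes listed at 1 in both y w libraries. Such genes were 22 of 23 calls with dfoxo[25J13], 47 of 61 with rel[E20] and 28 of 41 with atf3[A]. In the contrasts with atf3[76], over 11558 genes, 85%, 82% and 79% of 16-fold genes were recovered for the genotypes with dfoxo[25J13], rel[E20] and atf3[A], and 64%, 58% and 56% of 4-fold genes. Unchanged genes made up 11 of 160, 11 of 151 and 7 of 142 of those calls. The test of lists recovered 4 of 4 shifted lists and called 0 of the 136 others. Its simulated noise was independent between genes, and every member of the shifted list was moved by the same amount. It therefore cannot show how often correlated genes give a call without a shift.

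Alternatives covered the threshold, the pseudocount, genes overlapping another, filters on low values, centring the log2 fold changes on their median and quantile normalization. They also covered an intensity trend, the replicate number as a block, all 5 groups in one model and each library left out in turn. Another left out the 2 libraries of lowest relative depth, replicate 1 of y w and of atf3[76]. Each of these genotypes then has replicate 2 alone, so atf3[76] against y w compares single libraries. All other comparisons with y w or atf3[76] then rest on 1 reference library. Other steps used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6 and pandas 2.3.3.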

Results

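Transcript levels were measured by RNA-seq of total RNA from whole male larvae in 5 genotypes with 2 libraries each. The control was the y w stock, which carries the visible markers yellow and white. The mutant carried atf3[76], an allele of Activating transcription factor 3, a basic leucine zipper transcription factor. The other 3 genotypes added 1 copy of a second allele or element to atf3[76]. They are written foxo/+ for dfoxo[25J13], rel/+ for rel[E20] and atf3[A]/+ below. The labels place atf3[A] on chromosome 3, while Atf3 lies on X, which argues against an allele at that locus. FOXO is the forkhead factor held back by insulin signalling, and Relish is the NF-kB factor of the Imd immune pathway. Per the series' design, each genotype was measured relative to y w, and the title of the series names immune and metabolic homeostasis as the subject. All genotype names are those on the labels.

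Library quality was uneven. Relative depth was 0.52 in y w replicate 1 and 0.65 in atf3[76] replicate 1, against 0.97 to 1.01 in the 7 other libraries where it could be read. It could not be read in foxo/+ replicate 2. Of genes with a median of at least 10 FPKM in the other libraries, 3.84% were listed at 1 in y w replicate 1 and 4.54% in atf3[76] replicate 1, against 0.14% to 1.27% elsewhere. The 50 highest genes took 39.3% and 33.0% of all FPKM in the y w libraries and 25.8% to 35.2% in the others. Pearson correlations across genes between the 2 libraries of a genotype ran from 0.913 in atf3[76] to 0.96 in foxo/+. Libraries of y w and atf3[76] did not group by genotype. Replicate 1 of y w correlated with replicate 1 of atf3[76] at 0.947, against 0.936 for the y w pair. The replicate 2 libraries of these genotypes correlated at 0.946.

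The targeted genes were examined first. Atf3, listed as A3-3 (X, 1136772 to 1168682), had 3.71 ± 0.61 FPKM in y w (SD, n = 2), 9.90 ± 5.38 in atf3[76], 13.3 ± 0.279 in foxo/+, 12.2 ± 4.14 in rel/+ and 11.2 ± 2.33 in atf3[A]/+. Its log2 fold changes against y w were 1.12 ± 0.43 (SE), 1.61 ± 0.21, 1.45 ± 0.30 and 1.36 ± 0.29 in that order, and none was past the threshold (limma, lowest adjusted p = 0.115). The gene-level value was thus not lower in the libraries labelled atf3[76]; the lesion is not stated, so FPKM over the whole gene does not check that label. Rel (3R, 4869899 to 4873699) had 12.3 ± 2.77 FPKM in y w, 21.2 ± 0.335 in atf3[76], 20.9 ± 0.353 in foxo/+, 15.01 ± 2.46 in rel/+ and 17.5 ± 2.498 in atf3[A]/+. It overlaps another gene, so its values are uncertain. The rel/+ libraries lay below atf3[76] by a log2 difference of −0.48 ± 0.20, which was not past the threshold (limma, adjusted p = 0.485). Against y w the log2 fold change of Rel in rel/+ was 0.28, and its sign turned with other scaling, to −0.13 after centring and −0.07 after quantile normalization. For foxo (3R, 9882673 to 9913698) the y w libraries were listed at 1 and 7.64 FPKM, and the 8 others ran from 4.30 to 9.56, with 8.69 and 6.86 in foxo/+. The w gene (X, 2684631 to 2690499), which encodes an ABC transporter of eye pigment precursors, was listed at 1 in 8 libraries and at 33.7 and 26.3 FPKM in atf3[A]/+ (limma against y w, adjusted p = 0.0133). The y gene was listed at 1 in all 10.

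**Figure D1:**
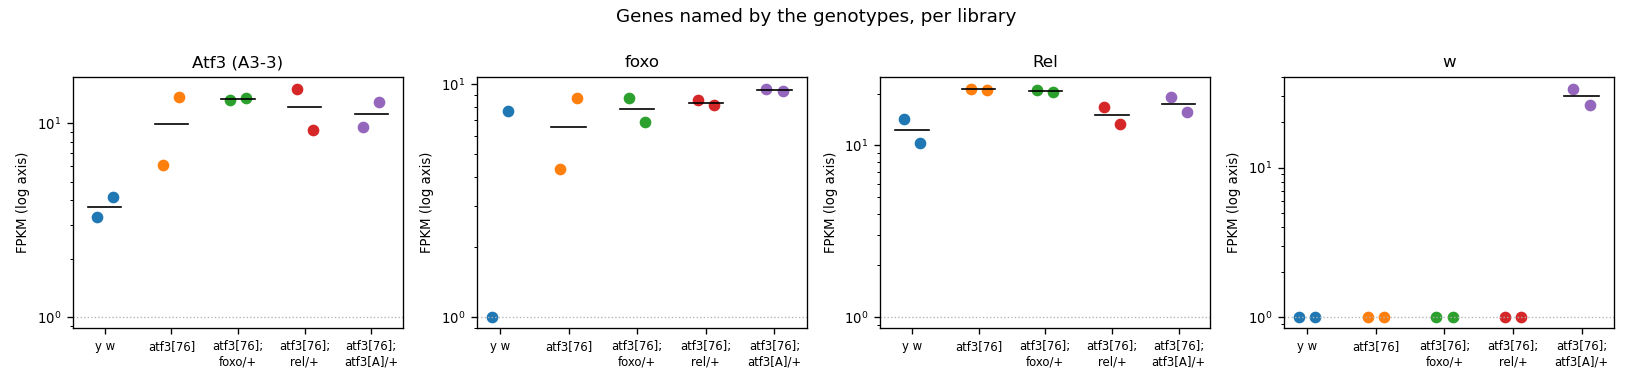
Expression of Atf3 (listed as A3-3), foxo, Rel and w in each library, in FPKM on a log axis, by genotype. Each point is 1 library, the dotted line is the floor of 1, and a bar is the mean of 2 libraries, drawn only where both are above 1; w stands above the floor only in atf3[A]/+, at 33.7 and 26.3.

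The comparison of atf3[76] with y w asks what the atf3 mutation does to the larval transcriptome. A cluster of lysozyme genes on 3L fell to a few percent of its control level. Lysozymes cleave bacterial cell walls, and these members are digestive enzymes of the midgut. LysD fell from 5599 ± 165 to 146 ± 17.2 FPKM (SD, n = 2 each), LysB from 4719 ± 333 to 134 ± 12.8, and LysE from 879 ± 155 to 27.3 ± 2.70. The control levels were 38.4, 35.3 and 32.2 times the mutant levels. The list of Toll pathway genes and immune-induced peptides lay higher and that of mitochondrial oxidative phosphorylation lower, though neither passed with correlated genes (adjusted p = 0.511 and adjusted p = 0.430 with an estimated correlation).

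In the limma test, 4 of 10983 genes were past the threshold, 1 higher and 3 lower. At an unadjusted p under 0.05 there were 391 genes, where chance would give 549, and 81.1% of them were higher. After centring the log2 fold changes on their median, the share higher was 68.9%. The log2 fold changes were −5.26 ± 0.26 (SE) for LysD (3L, 1210716 to 1211196), −5.13 ± 0.26 for LysB (3L, 1207370 to 1207868) and −4.95 ± 0.28 for LysE (3L, 1212826 to 1213406), each with an adjusted p of 0.0424. LysC, at 2031 ± 257 and 110 ± 8.61 FPKM, had a log2 fold change of −4.19 ± 0.26 and was not past the threshold over all genes (limma, adjusted p = 0.0571). Adjusted over the list alone, 4 of the 7 lysozymes measured were lower. The list's median of −4.19 was below all of the 10000 random lists (adjusted p = 0.00147; adjusted p = 0.252 with an estimated correlation). LysD and LysE overlap other genes and the family is similar in sequence, so the split of reads among members is uncertain; the FPKM summed over the 7 members was 14783 and 13924 in y w and 1811 and 1042 in atf3[76]. The gene called higher was mge, which encodes a subunit of the mitochondrial outer membrane import complex and overlaps another gene. It was listed at 1 in both y w libraries and at 40.5 and 41.4 FPKM in atf3[76].

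**Figure D2:**
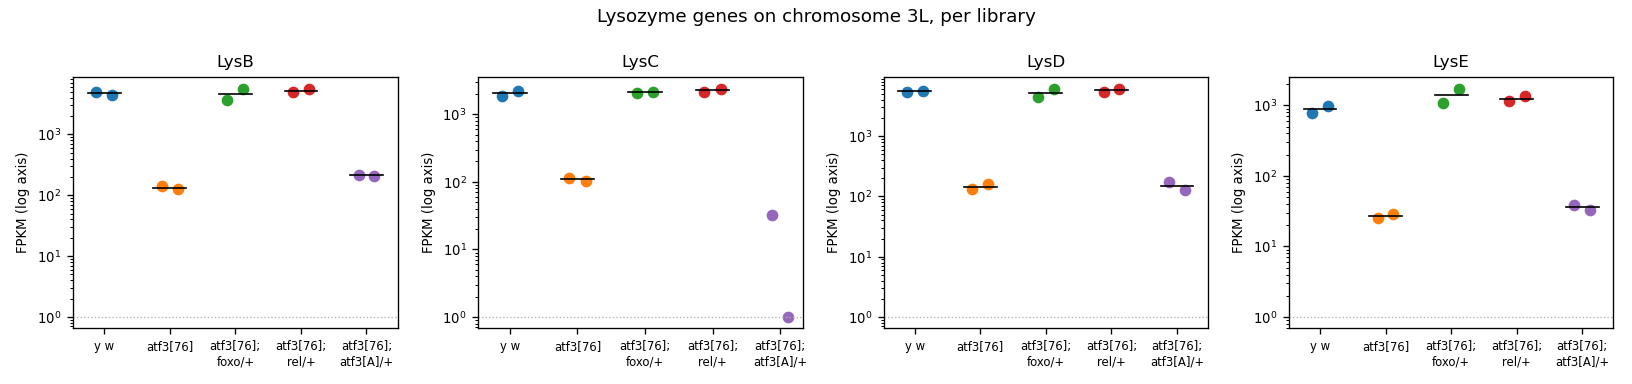
Expression of LysB, LysC, LysD and LysE in each library, in FPKM on a log axis, by genotype. Each point is 1 library, the dotted line is the floor of 1, and a bar is the mean of 2 libraries, drawn only where both are above 1; LysD averages 5599 in y w, 146 in atf3[76] and 150 in atf3[A]/+.

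Immune-induced peptides also stood far from their y w levels in atf3[76]. Drosomycin (Drs), an antifungal peptide, was listed at 2.66 and 1 FPKM in y w and at 95.1 and 138 in atf3[76], a log2 fold change of 5.42 ± 0.41 that missed the threshold over all genes (limma, adjusted p = 0.0797). For dro2, a Drosomycin-like peptide, both y w libraries were listed at 1 and those of atf3[76] at 35.1 and 52.0 FPKM. Immune-induced molecule IM3 had 3.63 ± 2.19 FPKM in y w and 138 ± 54.3 in atf3[76], and IM1 had 1.86 ± 1.01 and 55.2 ± 20.98. Of 25 Toll pathway genes and IM peptides, 6 were higher adjusted over the list alone and 0 over all genes tested, where 8 had an unadjusted p under 0.05 (limma). Their median of 0.44 was above all random lists (adjusted p = 0.00147; adjusted p = 0.511 with an estimated correlation), and without the 2 libraries of lowest relative depth, an alternative chosen after seeing the data, it did not pass (adjusted p = 0.0836). Of 16 antimicrobial peptides, 2 were higher adjusted over the list alone, Drs and dro2, and 0 over all genes, where 7 had an unadjusted p under 0.05 (limma). The list's median was 0.57 (adjusted p = 0.00147; adjusted p = 0.835 with an estimated correlation). The list of the Imd pathway and peptidoglycan recognition proteins had a median of 0.27, with 15 of 19 members above 0 (adjusted p = 0.0438; adjusted p = 0.759 with an estimated correlation), and did not pass without the 2 libraries of lowest relative depth (adjusted p = 0.315). The members past the threshold adjusted over the list alone were 2, PGRP-SC1a and PGRP-SC1b, both lower. PGRP-SC1a, an amidase that breaks down peptidoglycan, had 80.6 ± 25.0 FPKM in y w and 6.64 ± 4.44 in atf3[76]. Its log2 fold change of −3.52 ± 0.52 was lower adjusted over the list alone (adjusted p = 0.0123) and not over all genes (limma, adjusted p = 0.406).

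Some metabolic and detoxification lists lay lower in atf3[76]. Glutathione transferases, carbohydrate digestion and lipases did not pass, with medians of 0.028, 0.16 and 0.067 (adjusted p = 0.543, 0.473 and 0.952). Of 29 oxidative phosphorylation genes, 1 had a log2 fold change above 0, and the median was −0.40 (adjusted p = 0.00147; adjusted p = 0.430 with an estimated correlation). The libraries stood apart, at −0.11 in replicate 1 and −0.68 in replicate 2. Singly, 0 of them were past the threshold and 1 had an unadjusted p under 0.05 (limma). The median was −0.22 for fatty acid oxidation (adjusted p = 0.00415) and −0.22 for lipid synthesis and storage (adjusted p = 0.00676), with adjusted p = 0.549 and 0.430 with an estimated correlation. Fatty acid oxidation stood at −0.066 and −0.36 in the atf3[76] libraries and at 0.24 and −0.24 in those of y w. The median was −0.15 for cytochrome P450 genes (adjusted p = 0.00147; adjusted p = 0.430 with an estimated correlation) and −0.24 for heat shock genes (adjusted p = 0.00147; adjusted p = 0.751 with an estimated correlation). Among lists of other tissues, imaginal disc markers had a median of 0.25 (adjusted p = 0.0280; adjusted p = 0.968 with an estimated correlation) and salivary glue genes 0.43 (adjusted p = 0.0330; adjusted p = 0.838 with an estimated correlation). The y w libraries themselves stood apart in glue genes, at 0.57 and −0.57 from their mean. Peritrophic and mucin genes had a median of 0.48 (adjusted p = 0.00993; adjusted p = 0.430 with an estimated correlation) and JNK and wound genes 0.36 (adjusted p = 0.00415; adjusted p = 0.588 with an estimated correlation). The 2 atf3[76] libraries stood at 0.71 and 0.25 in the first of these and at 0.12 and 0.46 in the second. Without the 2 libraries of lowest relative depth, lipid synthesis (adjusted p = 0.162), imaginal disc markers (adjusted p = 0.201), peritrophic genes (adjusted p = 0.0744) and JNK and wound genes (adjusted p = 0.0642) did not pass, the P450 median turned to 0.038, still past the threshold against matched lists (adjusted p = 0.00271), and the glue median was 1.48. Lists that passed only then, where no correlation was estimated, were larval serum proteins (0.53), larval cuticle (−0.083), hemocyte markers (0.53), testis markers (0.50), female-specific genes (1.498) and cell cycle genes (0.51), with adjusted p between 0.00122 and 0.0389. Leaving out any 1 of the 4 libraries left 0 genes past the threshold in limma, with 293 to 414 at an unadjusted p under 0.05, while the log2 fold change of LysD stayed between −5.38 and −5.14. With all 5 groups in one limma model, an alternative chosen after seeing the data, 35 genes were past it, 31 higher and 4 lower. Leaving out the 2 libraries of lowest relative depth leaves 1 library each of y w and atf3[76]. That setting therefore has no replicates in this comparison.

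The comparison of foxo/+ with y w asks how the atf3 mutant transcriptome looks with 1 copy of foxo mutated. The main lysozymes stood near their y w levels: LysD had 5291 ± 1080 FPKM, LysB 4674 ± 1369 and LysE 1404 ± 451 (SD, n = 2). Cuticle proteins and oxidative phosphorylation genes lay lower as lists than matched random lists, and testis and germline markers higher. None of these passed with correlated genes (adjusted p = 0.252, adjusted p = 0.351 and adjusted p = 0.845 with an estimated correlation). The genes called higher were all listed at 1 in both y w libraries, among them Treh, the trehalose-cleaving enzyme.

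In limma, 23 of 11274 genes were past the threshold, 22 higher and 1 lower, and all 22 higher genes were listed at 1 in both y w libraries. Among genes above 1 in every library, which leaves out all of the 23, 183 were called higher and 42 lower. The gene called lower, snoRNA:Psi28S-1837b, had 10.95 and 11.3 FPKM in y w and was listed at 1 in both foxo/+ libraries. At an unadjusted p under 0.05 there were 2046 genes, 87.0% of them higher. After centring the log2 fold changes on their median, 42.6% were higher. The median log2 fold change over all genes was 0.32, and list percentiles are relative to matched genes of the same comparison. Treh was listed at 1 in both y w libraries and at 23.2 and 24.4 FPKM in foxo/+. Oscp, a subunit of the mitochondrial ATP synthase, was listed at 1 in both y w libraries and at 80.4 and 95.2. Also at 1 in both y w libraries were mge, at 45.1 and 47.8 FPKM in foxo/+, the G protein subunit gene Gbeta13F at 24.9 and 21.7, the ankyrin gene Ank at 24.7 and 21.9, Lmpt at 27.1 and 32.5, CG9084 at 32.0 and 24.6, CG6838 at 21.2 and 20.5, CG32549 at 24.3 and 20.1, and snoRNA:Me28S-U1688 at 49.1 and 50.3. In atf3[76], Treh, Oscp, Gbeta13F, Ank, Lmpt and CG9084 were listed at 1 in replicate 1 alone, with 22.7 FPKM for Treh and 99.5 for Oscp in replicate 2.

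Among the lists, 10 Toll pathway genes and IM peptides were higher and 1 (SPE, the Spätzle-processing enzyme) lower adjusted over the list alone, with 0 over all genes, where 12 had an unadjusted p under 0.05 (limma). The list's median of 0.55 did not pass the random-list test (adjusted p = 0.0549). Drs stood at 114 and 19.4 FPKM, with a log2 fold change of 4.16 ± 0.88 (limma, adjusted p = 0.188). Oxidative phosphorylation had a median of −0.74 (adjusted p = 0.00147; adjusted p = 0.351 with an estimated correlation), with 1 gene called, Oscp, in the opposite direction. Larval cuticle had −0.21 (adjusted p = 0.00147; adjusted p = 0.252 with an estimated correlation), and Lcp65Ab2, Lcp65Ae, TwdlO and Cpr65Ay were lower adjusted over the list alone. For trypsins and chymotrypsins it was −0.50 (adjusted p = 0.00233; adjusted p = 0.546 with an estimated correlation), and Jon44E and Jon99Ci were lower adjusted over the list alone. Fatty acid oxidation had −0.40 (adjusted p = 0.00147), lipid synthesis −0.21 (adjusted p = 0.0151), glutathione transferases −0.17 (adjusted p = 0.0172) and cytochrome P450 −0.19 (adjusted p = 0.00147); with an estimated correlation these were adjusted p = 0.430, 0.430, 0.430 and 0.351. Testis and germline markers had 0.64 (adjusted p = 0.00147; adjusted p = 0.845 with an estimated correlation), with dj, Mst35Bb, janB and fzo higher adjusted over the list alone. The 4 female-specific genes tested had 1.08 (adjusted p = 0.0478, and adjusted p = 0.813 with an estimated correlation). Heat shock genes had −0.068 (adjusted p = 0.0267, and adjusted p = 0.737 with an estimated correlation). The 2 foxo/+ libraries stood apart in female-specific genes (1.496 and 0.48), heat shock genes (0.15 and −0.18), larval cuticle (−0.49 and −0.17) and glutathione transferases (−0.47 and −0.12). Without the 2 libraries of lowest relative depth, trypsins (median −0.054, adjusted p = 0.165) and lipid synthesis (adjusted p = 0.0560) did not pass, and the medians were −0.17 for fatty acid oxidation, −0.38 for larval cuticle and −0.11 for heat shock genes. Larval serum proteins (0.96), glue genes (0.97) and muscle markers (−0.38) passed only then (adjusted p = 0.00224, 0.00339 and 0.00589). Leaving out y w replicate 1 left 0 genes past the threshold in limma (2712 at an unadjusted p under 0.05), and leaving out either foxo/+ library also left 0 (483 and 1494), while 184 were called without y w replicate 2. With all 5 groups in one model 45 genes were called, of which 6 were among the 23.

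The comparison of rel/+ with y w asks the same with 1 copy of Relish mutated. Drosomycin rose, from 2.66 and 1 FPKM in y w to 260 and 168 in rel/+. The detoxifying cytochrome P450 gene Cyp28d2 fell from 16.3 ± 0.315 to 2.40 ± 0.233 FPKM (SD, n = 2 each). The larval cuticle protein gene Lcp65Ab1, which overlaps another gene, fell from 12868 ± 405 to 3317 ± 166. Again LysD, LysB and LysE stood near their y w levels, with LysD at 5827 ± 468 FPKM, LysB at 5194 ± 424 and LysE at 1240 ± 132.

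In limma, 61 of 11354 genes were past the threshold, 58 higher and 3 lower; 47 of the higher genes were listed at 1 in both y w libraries. After quantile normalization the split was 41 higher and 8 lower. Among genes above 1 in every library it was 247 higher and 67 lower, and 8 of the 61 were among these. At an unadjusted p under 0.05 there were 2882 genes, 88.1% of them higher and 36.7% after centring, and the median over all genes was 0.40. Drs had a log2 fold change of 6.28 ± 0.40 (SE; limma, adjusted p = 0.0205), and CG15068, at 1 and 2.83 FPKM in y w and 110 and 79.9 in rel/+, of 5.10 ± 0.39 (limma, adjusted p = 0.0316). CG16775 rose from 4.43 ± 0.353 to 63.3 ± 8.27 FPKM, by 3.56 ± 0.20 (limma, adjusted p = 0.0167), and was named after its values were seen. Cyp28d2 fell by 2.34 ± 0.18 on the log2 scale (limma, adjusted p = 0.0316) and Lcp65Ab1 by 1.96 ± 0.18 (limma, adjusted p = 0.0492). Among genes listed at 1 in both y w libraries were Oscp at 94.1 and 82.8 FPKM in rel/+, mge at 42.0 and 49.8, the RNA-binding protein gene Hrb98DE at 43.8 and 47.4, CG15012 at 40.9 and 48.4, and the small nucleolar RNAs snoRNA:U14:30Ea, snoRNA:U14:30Eb, snoRNA:Me28S-G3253 and snoRNA:Me18S-A934. The third gene called lower, snoRNA:Psi18S-640f, had 18.0 and 18.7 FPKM in y w and was listed at 1 in both rel/+ libraries.

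The 2 rel/+ libraries differed widely in peptides under Imd control. The median of the antimicrobial peptide list against y w was 3.46 in replicate 1 and 0.43 in replicate 2; Diptericin (Dpt) stood at 74.6 and 7.01 FPKM, Metchnikowin (Mtk) at 102 and 9.24 and Attacin-A (AttA) at 73.3 and 7.75. Over both, the list's median was 1.90 (adjusted p = 0.00147; adjusted p = 0.818 with an estimated correlation), with 2 genes higher adjusted over the list alone and 1 over all genes, Drs. Of the Toll pathway genes and IM peptides, 9 were higher adjusted over the list alone and 0 over all genes, where 12 had an unadjusted p under 0.05 (limma). Their median of 0.52 did not pass (adjusted p = 0.169), while without the 2 libraries of lowest relative depth it was 0.80 and passed (adjusted p = 0.0113).

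Larval cuticle had a median of −0.57 in rel/+ (adjusted p = 0.00147; adjusted p = 0.252 with an estimated correlation), with Lcp9, Lcp65Ab1, Lcp65Ab2 and TwdlO lower adjusted over the list alone. Oxidative phosphorylation had −0.73 (adjusted p = 0.00147; adjusted p = 0.351 with an estimated correlation), trypsins −0.47 (adjusted p = 0.00233; adjusted p = 0.539 with an estimated correlation), and fatty acid oxidation −0.40 (adjusted p = 0.00233; adjusted p = 0.430 with an estimated correlation). For cytochrome P450 genes it was −0.15 (adjusted p = 0.00147; adjusted p = 0.351 with an estimated correlation). Glutathione transferases had −0.18 (adjusted p = 0.00993; adjusted p = 0.430 with an estimated correlation), with GstD5, GstD6 and GstD10 lower adjusted over the list alone. Testis and germline markers lay higher at 0.64 (adjusted p = 0.0155), salivary glue genes at 1.098 (adjusted p = 0.00233) and the 4 female-specific genes tested at 1.25 (adjusted p = 0.0151). With an estimated correlation these were adjusted p = 0.892, 0.993 and 0.813. Without the 2 libraries of lowest relative depth, trypsins (median −0.10, adjusted p = 0.0919) and glutathione transferases (0.064, adjusted p = 0.0545) did not pass. The medians were then 0.035 for cytochrome P450, still past the threshold (adjusted p = 0.00122), −0.14 for fatty acid oxidation and 2.01 for glue genes. Imaginal disc markers (0.75), larval serum proteins (0.82), muscle markers (−0.41) and lipid synthesis (0.016) passed only then (adjusted p = 0.0207, 0.0321, 0.00480 and 0.0489). Leaving out y w replicate 1 or either rel/+ library left 0 genes past the threshold in limma (4683, 1371 and 1189 at an unadjusted p under 0.05), and 236 were called without y w replicate 2. With all 5 groups in one model 42 genes were called, 13 of them among the 61.

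The comparison of atf3[A]/+ with y w sets the genotype that carries the element named atf3[A] against the control. Its main lysozymes were low, as in atf3[76]: LysD had 150 ± 31.0 FPKM, LysB 211 ± 0.655 and LysE 36.1 ± 4.18 (SD, n = 2), which were 37.4, 22.3 and 24.4 times below y w. Peptides of the Toll response rose, with Drs at 186 and 77.6 FPKM, IM3 at 66.7 ± 5.38 and IM10 at 24.4 and 20.6. TotC, a humoral stress peptide of the Turandot family, rose as well.

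In limma, 41 of 11068 genes were past the threshold, 34 higher and 7 lower. Of the 852 genes with an unadjusted p under 0.05, 50.9% were higher, and among genes above 1 in every library 87 were called higher and 83 lower. Of the 41 calls, 28 were listed at 1 in both y w libraries and 4 in both atf3[A]/+ libraries. The log2 fold changes were −5.23 ± 0.28 (SE) for LysD, −4.47 ± 0.25 for LysB and −4.56 ± 0.28 for LysE, each with a limma adjusted p of 0.0126. The list had 5 members lower adjusted over the list alone and a median of −4.47 (adjusted p = 0.00147; adjusted p = 0.305 with an estimated correlation). Drs rose by 5.49 ± 0.53 (limma, adjusted p = 0.0365), IM3 by 3.95 ± 0.40 (limma, adjusted p = 0.0421) and IM10, at 1.32 and 1 FPKM in y w, by 3.44 ± 0.26 (limma, adjusted p = 0.0167). Listed at 1 in both y w libraries, dro2 stood at 28.4 and 25.0 FPKM (limma, adjusted p = 0.0133) and IM4 at 11.8 and 15.3 (limma, adjusted p = 0.0327). CG17352, at 11.6 and 9.43 FPKM in y w (limma, adjusted p = 0.0434), CG7381, at 38.2 and 28.3, and CG42306, at 18.0 and 14.1, were called lower and were listed at 1 in both atf3[A]/+ libraries. The rule also named Hexo1, a hexosaminidase gene, CG15012, Hrb98DE and mge, the last at 33.1 and 30.3 FPKM, all at 1 in both y w libraries, and 4 small nucleolar RNAs higher and 1 lower.

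**Figure D3:**
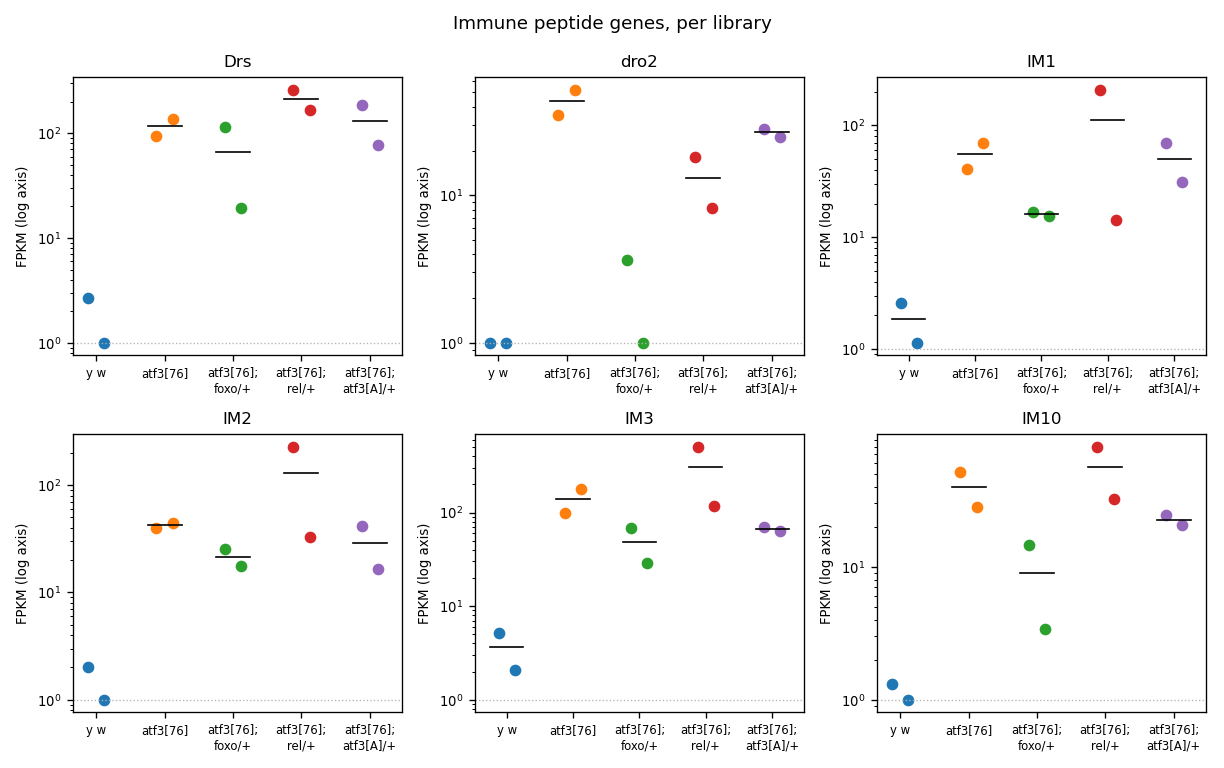
Expression of 6 immune peptide genes (Drs, dro2, IM1, IM2, IM3 and IM10) in each library, in FPKM on a log axis, by genotype. Each point is 1 library, the dotted line is the floor of 1, and a bar is the mean of 2 libraries, drawn only where both are above 1; Drs lies at 2.66 and 1 in y w and at 77.6 to 186 in atf3[A]/+.

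Of 25 Toll pathway genes and IM peptides in atf3[A]/+, 3 were called over all genes and 8 were higher and 1 lower adjusted over the list alone (Fisher's exact test, adjusted p = 0.00479). Their median was 0.28 (adjusted p = 0.0151; adjusted p = 0.588 with an estimated correlation), with 0.58 in replicate 1 and 0.010 in replicate 2, and 0.49 without the 2 libraries of lowest relative depth. Of 16 antimicrobial peptides, 2 were called, and 3 were higher and DptB lower adjusted over the list alone; the median was 0.33 (adjusted p = 0.0136; adjusted p = 0.838 with an estimated correlation). JAK-STAT and stress peptides had a median of 0.45 (adjusted p = 0.0151; adjusted p = 0.551 with an estimated correlation). Within that list TotC rose by 3.01 ± 0.26 (limma, adjusted p = 0.0230), and TotA had a log2 fold change of 2.66 ± 0.29 that missed the threshold (limma, adjusted p = 0.0510). Ecdysone response genes had 0.39 (adjusted p = 0.00147; adjusted p = 0.722 with an estimated correlation) and heat shock genes 0.50 (adjusted p = 0.00233; adjusted p = 0.813 with an estimated correlation). Both stood higher in replicate 1, at 0.76 and 0.87, than in replicate 2, at 0.015 and 0.024. Trypsins had −0.74 (adjusted p = 0.00147; adjusted p = 0.717 with an estimated correlation) and oxidative phosphorylation −0.80 (adjusted p = 0.00147; adjusted p = 0.430 with an estimated correlation). Glutathione transferases had −0.53 (adjusted p = 0.00336; adjusted p = 0.430 with an estimated correlation), with GstD2, GstD4, GstD6, GstD7 and GstE1 lower adjusted over the list alone. Testis and germline markers lay lower here, at −0.25 (adjusted p = 0.0441; adjusted p = 0.813 with an estimated correlation), with −0.037 and −0.58 in the 2 libraries. Other tissue lists lay higher, with medians of 0.49 for nervous system markers (adjusted p = 0.0105), 0.32 for imaginal disc markers (adjusted p = 0.0203) and 0.48 for salivary glue genes (adjusted p = 0.00600); with an estimated correlation these were adjusted p = 0.697, 0.588 and 0.896. The 2 libraries stood apart in imaginal disc markers (0.52 and 0.084) and glue genes (1.06 and 0.33). JNK and wound genes had 0.35 (adjusted p = 0.0260; adjusted p = 0.551 with an estimated correlation) and carbohydrate digestion 0.29 (adjusted p = 0.0259; adjusted p = 0.588 with an estimated correlation). Without the 2 libraries of lowest relative depth, trypsins (median −0.19, adjusted p = 0.484), heat shock genes (0.24, adjusted p = 0.120) and nervous system markers (0.43, adjusted p = 0.0669) did not pass, and the glue median was 1.48. Larval serum proteins (0.37), larval cuticle (−0.23), hemocyte markers (0.48), female-specific genes (0.72), cell cycle genes (0.47) and cytoskeleton and junction genes (0.48) passed only then, with adjusted p between 0.00122 and 0.0362. Leaving out any 1 of the 4 libraries left 0 genes past the threshold in limma, with 347 to 1068 at an unadjusted p under 0.05 and LysD between −5.44 and −5.02, and 26 were called with all 5 groups in one model, 11 of them among the 41.

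**Figure D4:**
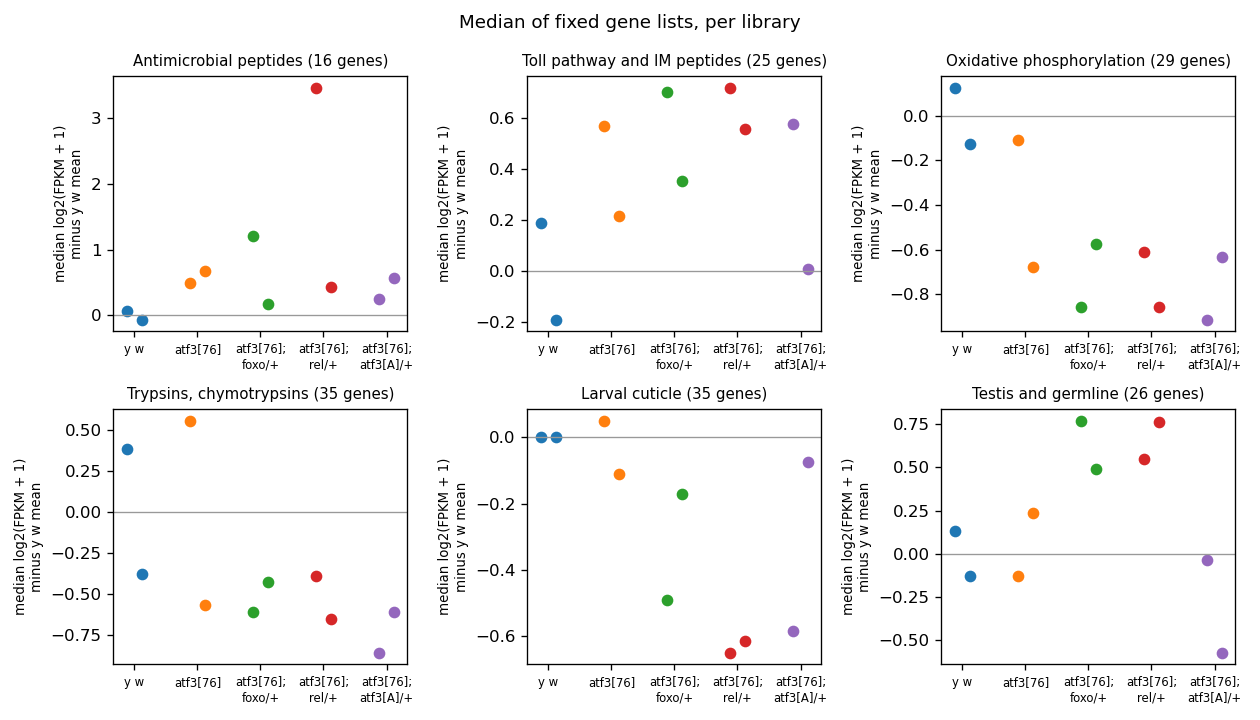
Median log2(FPKM + 1) of 6 gene lists in each library minus the mean of the y w libraries, by genotype, on linear axes with a line at 0. Each point is 1 library; the antimicrobial peptide list stands at 3.46 and 0.43 in the 2 rel/+ libraries.

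Putting a second allele into atf3[76] asks which of its features depend on foxo, Relish or the added atf3 element. The direct contrasts with atf3[76] show which genes differed between these genotypes. No genotype carried a second allele or element without atf3[76]. The labels place each of them on the chromosome that also holds the lysozyme cluster. The contrasts therefore cannot separate an effect of the allele or element from one of the chromosome it came with. LysB, LysD and LysE stood far above their atf3[76] levels in foxo/+ and rel/+, and none of them was past the threshold in atf3[A]/+ against atf3[76]. Against atf3[76], LysE was higher in foxo/+ by 5.60 ± 0.26 on the log2 scale (SE; limma, adjusted p = 0.000298), LysD by 5.16 ± 0.22 and LysB by 5.09 ± 0.22. In rel/+ the differences were 5.45, 5.31 and 5.27. LysP, a lysozyme known from the salivary glands, was listed at 1.77 and 1 FPKM in y w, at 1 in both atf3[76] libraries, at 9.95 and 9.05 FPKM in foxo/+ and at 13.3 and 21.2 in rel/+ (limma, rel/+ against atf3[76], adjusted p = 0.00852).

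In the contrast of foxo/+ with atf3[76], 6 of 11558 genes were past the threshold, 5 higher and 1 lower, and after quantile normalization 5 were higher and 0 lower, with 612 at an unadjusted p under 0.05 (limma). Besides the 3 lysozymes they were CG6838 (21.2 and 20.5 FPKM) and CG8136 (14.2 and 11.6), both listed at 1 in the atf3[76] libraries, and an ABC transporter gene listed under the identifier FBgn0010549, which fell from 11.03 ± 0.501 to 2.83 ± 0.0368 FPKM (SD, n = 2 each; limma, adjusted p = 0.0442). In the contrast of rel/+ with atf3[76], 10 genes were past it, 9 higher and 1 lower, and after centring 8 higher and 3 lower. Syndecan (Sdc), a heparan sulphate proteoglycan, was listed at 1 in both atf3[76] libraries and at 20.98 and 17.7 FPKM in rel/+, and Cyp28d2 was lower than the 11.9 ± 0.0682 FPKM of atf3[76] by a log2 difference of −1.92 ± 0.18 (limma, adjusted p = 0.0193). In the contrast of atf3[A]/+ with atf3[76], 9 genes were past it, 6 higher and 3 lower. CG13324 fell from 462 ± 98.6 to 63.7 ± 3.04 FPKM (limma, adjusted p = 0.00510), and CG5506 from 365 ± 25.8 to 100.1 ± 6.07 (limma, adjusted p = 0.0271). CG6686, at 7.78 and 10.6 FPKM in atf3[76], was listed at 1 in both atf3[A]/+ libraries, and w and Sdc were listed at 1 in atf3[76] and above 20 FPKM in atf3[A]/+. Without the 2 libraries of lowest relative depth the 3 contrasts gave 23, 20 and 22 genes, with 11, 11 and 9 higher and 12, 9 and 13 lower. Without atf3[76] replicate 1 alone 7, 9 and 6 were higher and 14, 10 and 13 lower. Without 1 library at a time the counts ran from 8 to 151, from 11 to 169 and from 11 to 144, the highest without atf3[76] replicate 2.

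Calls were compared between genotypes. Genes called higher in both foxo/+ and rel/+ numbered 17, where independent lists would share 0.0959 and unchanged groups against the same controls shared 0. There were 12 for foxo/+ and atf3[A]/+ and 21 for rel/+ and atf3[A]/+, where independent lists would share 0.0529 and 0.159. All 17, all 12 and 20 of the 21 were listed at 1 in both y w libraries. The simulation draws normal values around 1 mean per gene and has no failed estimates listed at 1. Its shared count of 0 therefore cannot say whether the shared controls account for such genes. LysB, LysD and LysE were the 3 genes called lower in both atf3[76] and atf3[A]/+. Across genes, which are not independent replicates, log2 fold changes correlated most between foxo/+ and rel/+ (Pearson r = 0.882, covariance 0.328; 0.501 and 0.0937 in the simulation) and least between atf3[76] and atf3[A]/+ (r = 0.550, covariance 0.160; 0.4996 and 0.0935 in the simulation). For that last pair Spearman's rho was 0.455, and 0.456 in the simulation. The 2 control libraries were not split between comparisons, so part of each excess may come from them. The simulation also gives all libraries the same spread for a gene, whereas y w replicate 1 had a relative depth of 0.52. Noisier controls would raise the correlation of unchanged groups above the simulated values. Of 36 tests of calls by chromosome arm or near Atf3, foxo and Rel, 0 were past the threshold (Fisher's exact test) and 5 had an unadjusted p under 0.05, the lowest being 3L in atf3[76], which held all 4 calls (p = 0.00145, adjusted p = 0.0523).

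Of 140 list tests, 48 were past the threshold, 0 with an estimated correlation (camera in limma, lowest adjusted p = 0.252) and 61 with a preset one. The camera values are adjusted over 245 tests, which include the contrasts with atf3[76]; over the 140 alone the lowest was 0.192 with an estimated correlation. The authors' deposited tables hold more calls than limma made here. They list 669 higher and 176 lower records for atf3[76], 3099 and 449 for foxo/+, 4047 and 502 for rel/+, and 1044 and 907 for atf3[A]/+. The lowest fold change among the authors' calls was 1.5.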

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

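The tests in this part were chosen after the result was seen, except the test of a genotype difference for genes listed at 1 in y w and the test of a shared haplotype of chromosome 3.

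What brought these results forward is a difference between genotypes, tested directly against atf3[76] with limma on the log2 scale (SE beside each value). In foxo/+, LysE was higher than in atf3[76] by 5.60 ± 0.26 (adjusted p = 0.000298), LysD by 5.16 ± 0.22 and LysB by 5.09 ± 0.22 (both adjusted p = 0.000245). CG6838 differed by 3.45 ± 0.15 and CG8136 by 2.79 ± 0.14 (adjusted p = 0.000480), both against genes listed at 1, so these sizes measure no fold. The ABC transporter gene FBgn0010549 differed by −1.65 ± 0.17 (adjusted p = 0.0442). In rel/+, LysE differed by 5.45, LysD by 5.31 and LysB by 5.27, and Cyp28d2 by −1.92 ± 0.18 (adjusted p = 0.0193). Against genes listed at 1 in both atf3[76] libraries, CG6838 differed by 3.47, snoRNA:Psi18S-1295 by 3.37 ± 0.22 (adjusted p = 0.00262), Sdc by 3.34 ± 0.14, LysP by 3.15 ± 0.26 (adjusted p = 0.00852) and snoRNA:Psi18S-1086 by 2.15 ± 0.19 (adjusted p = 0.0141). In atf3[A]/+, CG13324 differed by −2.82 ± 0.20 (adjusted p = 0.00510) and CG5506 by −1.86 ± 0.19 (adjusted p = 0.0271). CG6686 was at 1 in both atf3[A]/+ libraries and differed by −2.34 ± 0.18 (adjusted p = 0.00587). Against genes at or near 1 in atf3[76], w differed by 3.94 ± 0.15, Sdc by 3.45, CG6838 by 3.14, snoRNA:Psi18S-1086 by 2.40, CG14610 by 2.18 (adjusted p = 0.00887) and snoRNA:Me28S-U1230 by 2.14 (adjusted p = 0.00140).

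The first pattern is the low level of LysB, LysD and LysE in atf3[76] and atf3[A]/+ beside control levels in foxo/+ and rel/+. The tables argue against failed estimates, since the lowest of the 3 genes in those 4 libraries was 25.4 FPKM, and against reads moved between paralogs, since the lysozyme FPKM summed there to 7.3% of that in the other 6 libraries. Less midgut tissue is argued against by the trypsin list, whose median was 0.04 in atf3[76] and −0.74 in atf3[A]/+, far from the lysozyme change, although trypsins of the 2 atf3[76] libraries stood apart at 0.55 and −0.57. A chromosome 3 haplotype shared by the pair stays open: beside the lysozymes, 7 genes with the same pattern lay on that chromosome and 8 elsewhere (exact test, p = 1, against 44.0% of other genes), which is too few to decide. The labels place atf3[A] on chromosome 3 as they do dfoxo[25J13] and rel[E20], and LysD stayed at 172 and 128 FPKM in atf3[A]/+, so an introduced chromosome 3 was present with low and with high lysozymes; a 3L variant near them and an effect of foxo or Relish dose may each account for it, and neither was tested apart from the other.

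The second pattern is that 59 genes called higher than y w were listed at 1 in both y w libraries. Failed estimates are a candidate explanation: among genes at 10 or more FPKM in 9 libraries, 70 were at exactly 1 in the tenth and 2 between 1 and 3, so this floor takes genes that other libraries show as abundant. A genotype difference for the set was set against 2 genes at 1 in both y w libraries and at 10 or more in the other 8, where y w replicate 1 and atf3[76] replicate 1 shared 43; the bound written beforehand would have excluded it, but only 2 of the 59 genes fall in that set, so it was the wrong bound and decides nothing. Of the 59, 40.7% were listed at 1 in both libraries of at least 1 genotype with atf3[76], and 47 were at 1 in atf3[76] replicate 1. From the listed values alone, failed estimates and a difference of genotype cannot be told apart gene by gene. A silent gene and a failed estimate share the listed value. The authors' calls also mark between 738 and 1032 records per comparison as failed in quality control. Those marks were not looked up for the 59 genes.

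The third pattern is the broad upward shift of foxo/+ and rel/+ against y w, with medians over all genes of 0.32 and 0.40. A low level confined to y w is argued against, as the median shift against atf3[A]/+ was still 0.31 in rel/+ and 0.23 in foxo/+. The atf3[A]/+ median against y w was 0.0052, so that genotype lay as low as y w. A low level of both sets of libraries is thus not excluded. Median FPKM was 4.45 and 3.79 in the y w libraries and 5.49 and 3.86 in those of atf3[A]/+. Against atf3[76] the median shifts were 0.24 in rel/+ and 0.16 in foxo/+. A difference of scale between libraries stays open: after centring, 36.7% of genes with an unadjusted p under 0.05 were higher in rel/+ and 42.6% in foxo/+. Centring removes a shift common to all genes whatever its source, so these shares cannot decide. More testis and imaginal disc tissue also cannot be told apart from regulation, with the 2 marker lists between percentiles 94.1 and 100, and the disc list in rel/+ past the threshold without the 2 libraries of lowest relative depth (adjusted p = 0.0207). The disc list also lay at percentile 99.6 in atf3[76] and 99.7 in atf3[A]/+, where the medians over all genes were 0.11 and 0.0052. The testis list lay at percentiles 22.6 and 0.73 in these genotypes. A high disc percentile was thus not particular to the shifted genotypes. The genotype itself remains an untested explanation.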

How the results depend on the processing

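The settings chosen after the data were seen were all 5 groups in one model, leaving out the 2 libraries of lowest relative depth, genes above 1 in every library, a mean FPKM of at least 5, the intensity trend, quantile normalization, crossed pairing, camera, the threshold for the targeted genes and, in the contrasts with atf3[76], the pseudocount, the replicate block and each library left out. Of 802 values of 85 results on single genes under other settings, 616 kept their direction and side of the threshold, 181 lost the threshold, 3 gained it and 2 changed sign; with 1 library left out these were 289, 193, 1 and 1 of 484. The changes of sign were Rel in rel/+, at −0.13 after centring and −0.065 after quantile normalization, and foxo in atf3[76], which ran from −0.27 without y w replicate 1 to 1.84 without y w replicate 2. In the order atf3[76], foxo/+, rel/+ and atf3[A]/+, the counts of 4, 23, 61 and 41 genes called against y w became 0, 0, 0 and 1 at an adjusted p of 0.01, and 1, 8, 24 and 13 without genes overlapping another. With genes above 1 in every library they were 51, 225, 314 and 170, which removes the genes listed at 1. With the replicate number as a block they were 34, 42, 170 and 0. The labels do not say that numbers pair samples, so the block has no basis in the design. Replicate differences correlated between genotypes at −0.22 to 0.47 over 7417 genes, and the highest value was for y w with atf3[76]. A mean FPKM of at least 5 gave 9 in atf3[76], 35 in foxo/+ and 74 in atf3[A]/+. All 5 groups in one model gave 35, 45 and 26 in atf3[76], foxo/+ and atf3[A]/+, and without the 2 libraries of lowest relative depth 42 and 36 in the first pair. In atf3[76] a pseudocount of 0.1, the intensity trend and quantile normalization each gave 0, with 369, 387 and 409 genes at an unadjusted p under 0.05 (limma). In foxo/+ a pseudocount of 0.1 gave 40, the intensity trend 13 and centring 14. With each library left out, counts ran from 0 to 0 in atf3[76], from 0 to 184 in foxo/+, from 0 to 236 in rel/+ and from 0 to 0 in atf3[A]/+; a lone library is then assumed to vary like the other group. The 0 counts without a library had 293 to 4683 genes at an unadjusted p under 0.05 (limma), and the lower number of libraries is part of that loss. In the contrasts with atf3[76], a pseudocount of 0.1 gave 11 for foxo/+, and a crossed pairing, which blocks replicate 1 of one genotype with replicate 2 of the other, gave 0 for foxo/+ (1066 at an unadjusted p under 0.05, limma) and 13 for atf3[A]/+, 3 of them among the 9. Genes above 1 in every library gave 4 for rel/+ and 3 for atf3[A]/+, and quantile normalization gave 16 for atf3[A]/+. Without the 2 libraries of lowest relative depth the contrasts gave 23, 20 and 22, and with each library left out 8 to 151, 11 to 169 and 11 to 144, highest without atf3[76] replicate 2. The block gave 5, 8 and 9 there. Of the 48 list tests past the threshold, 31 were past 0.01, and 0 with camera and an estimated correlation, adjusted over 245 tests or over the 140 alone; without the 2 libraries of lowest relative depth 35 were still past it, 13 were lost and 20 others gained. Genes called in several comparisons went from 32 to 0 at 0.01, and calls among the targeted genes from 1 to 0. The cause of the changes was not tested, except where the text gives it. Planned but not run were a filter at 1 FPKM, which the floor makes empty for calls and for correlations, an adjustment from deposited p-values, a count model, and a standard error without the shared control, which the direct contrast replaces. Shallow y w replicate 1 limits all 4 comparisons with y w.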

Other observations

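The genes below, and the test of the hypothesis that ends this part, were chosen after the result was seen; they come from the model of all 5 groups, where 31 of the 45 genes called in foxo/+ and 26 of the 35 in atf3[76] were above 1 in some library of both groups.

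A set of abundant genes, all but Fst outside the fixed lists, was several times higher in the atf3[76] larvae, and many of them lay closer to y w in atf3[A]/+. CG13323 had 94.5 ± 26.5 FPKM in y w (SD, n = 2), 668 ± 111 in atf3[76], 455 ± 33.0 in foxo/+, 434 ± 52.1 in rel/+ and 175 ± 6.70 in atf3[A]/+; in that model it was called in the first 3 mutants (limma, adjusted p = 0.00846, 0.0170 and 0.0167) and not in atf3[A]/+ (limma, adjusted p = 0.263). Its neighbour in name, CG13324, had 118 ± 16.2, 462 ± 98.6, 306 ± 29.2, 295 ± 30.8 and 63.7 ± 3.04 FPKM in the same order. CG5506 had 88.3 ± 1.69, 365 ± 25.8, 411 ± 95.9, 326 ± 14.5 and 100.1 ± 6.07 (limma in that model, adjusted p = 0.0121, 0.00916, 0.0145 and 0.743). Frost (Fst), a gene induced by cold, had means of 143, 354, 388, 429 and 274 FPKM, CG9568 of 75.4, 229.9, 352 and 298 before 105 in atf3[A]/+, and CG10912 of 128, 436, 388, 362 and 207. The next 2 genes encode glucose dehydrogenase-like oxidoreductases, and both overlap another gene. CG9509 rose from a mean of 7.02 FPKM in y w to 24.6, 23.8, 19.2 and 24.3 in the 4 mutants (limma in that model, adjusted p = 0.0156, 0.0170, 0.0279 and 0.0132). CG9512 had 57.3 FPKM in y w and 24.5, 19.0, 16.3 and 28.9 in the mutants, and was called lower in foxo/+ and rel/+ (limma in that model, adjusted p = 0.0423 and 0.0254).

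Values of further genes follow, none of them past the threshold in the contrasts with atf3[76]. PGRP-SC1b had means of 66.2 FPKM in y w, 4.33 in atf3[76], 13.4 in foxo/+, 102 in rel/+ and 122 in atf3[A]/+, and PGRP-SC1a had 132 ± 19.8 in rel/+ and 158 ± 47.2 in atf3[A]/+ (SD, n = 2). PGRP-SC2 and PGRP-SD were higher in atf3[A]/+ adjusted over the Imd list alone, with log2 fold changes of 1.96 and 1.49, and PGRP-SB1 was lower at −1.72. CG4783 had means of 26.0 FPKM in y w, 4.13 in atf3[76], 22.1 in foxo/+, 27.6 in rel/+ and 1.92 in atf3[A]/+. In foxo/+ replicate 1 the antimicrobial peptide list also stood above its partner, at 1.21 and 0.17. In rel/+, markers of imaginal discs (wg, Dll, hh, en, dpp, bab2 and tsh) and the JNK and wound genes puc, Mmp2, Ddc, Gadd45 and Pvf1 were higher adjusted over the list alone, while neither list passed the random-list test (adjusted p = 0.154 and 0.147); without the 2 libraries of lowest relative depth the imaginal disc list did (adjusted p = 0.0207).

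A hypothesis from the first set is that atf3[A] lowers genes that are higher in the other atf3[76] genotypes. It was computed over 34 genes called higher than y w in foxo/+ or rel/+ in the 5-group model. Of these, 11 had been picked after their values were seen, among them CG13323, CG9568, CG10912 and Fst, and CG5506 also prompted it. Their median log2 difference of atf3[A]/+ from atf3[76] was −0.72, below all matched random lists (median −0.21), and 31 of the 34 were lower. Because those genes were seen to have the pattern, the value restates the observation and does not decide the hypothesis, and the labels do not say what atf3[A] is.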
